A study of Mus musculus with 8 samples.

How the data were processed

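RNA was sequenced from 8 mouse samples, 4 given saline (control) and 4 given alcohol, with the groups and replicate numbers taken from the sample labels. The labels give liver as the tissue of every sample and also name AML12, a line of mouse hepatocytes, as the cell line. The values hold transcripts of Kupffer, endothelial and red blood cells, which liver tissue has and a hepatocyte line alone does not. The design text describes C57BL/6 mice, an inbred laboratory strain, and an alcohol-fed group. All 8 samples carry 1 batch label. The design text says that no sample is a duplicate, but nothing in the sources used here says that each sample came from a separate animal, so the p-values measure the spread between these samples. Per the labels' protocols, total RNA was purified on columns and mRNA libraries were prepared with a SMARTER kit. Whether the libraries kept strand, and which aligner, counter and annotation were used, are not given in the sources used here. The submitters' processing notes name the genome builds GRCm38 and mm10.

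The deposited values are FPKM (fragments scaled to gene length and to the library total), 1 column per sample for 21049 gene symbols, and each symbol appears once. Every column was used. In FPKM each library is divided by its own total, so a change in the most abundant transcripts moves the values of all the others. Whole reads were recovered from the FPKM values. A library total and a gene length were found that turned the values of 21046 genes (99.99%) into whole numbers in all 8 samples, to a tolerance of about 1e-06 of a read. The smallest such length was taken, so for genes with few reads the recovered length and reads may be a fraction of the true ones. The library totals recovered in this way were 33872595 to 38407511 reads, and 99.80% to 99.92% of each total lay in the 21046 genes with recovered reads. Mt2 is listed but has no recovered reads, so its reads are not in that share. Every alcohol total was above every control total. These reads were used for depth, for shares of reads, for counting intervals and for 1 alternative test. Intervals on reads are 95% Poisson intervals and cover counting error only.

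The groups were compared with limma 3.58.1 in R 4.3.3, on log2(FPKM + 1), for the 9228 genes with a mean of at least 1 FPKM over the 8 samples. The fit had a term for the group, moderated variances with a trend on mean level, and 2-sided p-values with Benjamini-Hochberg adjustment over the tested genes at a threshold of 0.05. A log2 change is the alcohol mean minus the control mean on the log2(FPKM + 1) scale, which understates the change of genes with low values. H19 lay below the expression minimum and was fitted with all 21049 genes. H19, Sirt1 and Mir22hg were also compared by an exact 2-sided permutation test of the difference in means over all 70 assignments of 4 samples to each group, whose smallest possible p is 0.0286. Mature miR-22 is not measured by an mRNA library, so its host transcript Mir22hg was read in its place.

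Gene lists were fixed before the data were examined: 25 lists of pathways and 14 lists of cell type or sex markers. Lists with at least 5 tested members (33 of 39) were compared with the other genes by camera in limma, with a preset inter-gene correlation of 0.01, and adjusted over the 33 lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were alternatives. The genes named were also set by a rule fixed before the data were examined. The rule takes H19, Sirt1 and the miR-22 host gene whatever their values. It takes the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap, leaving out unnamed and predicted genes. It also takes up to 4 members of each list by smallest p, or the 2 most abundant where none passes. Genes named outside that rule are said to have been chosen after their values were seen. Members of the Mup, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Saa, Orm, Hba, Hbb, Serpina3 and Serpina1 families are near-identical in sequence, so how reads were divided within each family is uncertain.

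Coordinates, biotypes and overlaps come from GENCODE M21 on GRCm38, matched by symbol. Of the tested genes, 8899 had 1 gene of the same symbol there. Across those genes the recovered lengths and the annotated exon lengths had a Spearman rho of 0.767, with a median ratio of 0.842.

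The replicates were compared before averaging. Spearman correlations of log values were 0.961 to 0.973 within groups and 0.947 to 0.953 between groups. The chi-square per gene between recovered reads, which sampling noise alone would hold near 1, ran from 8.04 to 167 within groups. The 8.04 was alcohol replicates 2 and 4, which were far more alike than any other pair (next lowest 41.8). Each sample was counted once, and if those 2 samples share a source the p-values are too small. Without replicate 2 of the alcohol group 3754 genes were higher and 1115 lower, and without replicate 4 they were 3704 and 1084. The procedure was tested on simulated data with the means of the control samples, the spreads of both groups, independent genes and 8720 genes tested. For the alcohol and control comparison it recovered 29.7% of 64 genes changed 1.5-fold, 83.9% of 62 genes changed 2-fold and 98.3% of 58 genes changed 4-fold. It made 7.25% false calls, and 0 calls when no gene was changed. In the real comparison 57.2% of tested genes were called, a far larger share than was changed here, so these rates need not hold for it.

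The alternatives planned before the data were examined were pseudocounts of 0.1 and 5, no expression minimum, a minimum of 5 FPKM, quantile normalization, TPM scale, median-of-ratios scaling between samples, a replicate block, variances without a trend, robust variances, sample weights, and leaving out each sample in turn. Voom in limma on the recovered reads and removal of a gene length trend were added after seeing the data. Plots and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.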

Results

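Transcripts were measured by RNA sequencing in 4 control (saline) and 4 alcohol samples labelled as mouse liver, to ask what alcohol feeding changes and, from the study's title, how the long non-coding RNA H19, miR-22 and the deacetylase Sirt1 behave. Library totals recovered from the deposited FPKM values were 33872595 to 34789814 reads in the control samples and 37132631 to 38407511 reads in the alcohol samples. Albumin (Alb), the main secreted protein of hepatocytes, stood at 36840 ± 1362 FPKM (SD, n = 4) in controls and 40290 ± 4354 FPKM with alcohol. The libraries also held transcripts that a culture of hepatocytes alone would not supply. In controls the Kupffer cell lectin Clec4f stood at 10.6 ± 5.09 FPKM, the macrophage protein Cd5l at 17.8 ± 10.9 FPKM, the endothelial lectin Clec4g at 9.95 ± 2.07 FPKM and the haemoglobin gene Hbb-bs at 72.5 ± 22.4 FPKM. These 5 genes were chosen after their values were seen, and reads of the haemoglobin genes are uncertain one by one.

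Alcohol samples differed from controls across much of the transcriptome, and Cyp2b10 had the largest rise on the log2(FPKM + 1) scale. Cyp2b10, a drug-metabolizing cytochrome of the liver, rose from 0.441 ± 0.247 to 537 ± 126 FPKM (SD, n = 4 per group). Its log2 change was 8.54 ± 0.17 (SE), with a limma adjusted p of 3.76e-10. The stress transcription factor Atf3 rose from 0.246 ± 0.0902 to 106 ± 67.7 FPKM, and Trib3, a pseudokinase induced by the integrated stress response, from 2.21 ± 1.18 to 165 ± 26.4 FPKM. Metallothionein Mt2, a metal-binding protein, rose from 54.1 ± 17.3 to 1183 ± 616 FPKM. The largest falls on that scale were in major urinary proteins, led by Mup15 at 540 ± 232 FPKM in controls and 41.1 ± 22.6 FPKM with alcohol, a log2 change of -3.79 ± 0.49.

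The other 8 of the 12 largest rises included Cyp2a22, another liver cytochrome, with a log2 change of 5.04, the kinase Sgk1 (4.37) and the cell cycle inhibitor Cdkn1a (4.32). The rest were the insulin-like growth factor binding protein Igfbp1 (4.16), the glutathione transferase Gstm3 (4.07), the heme oxygenase Hmox1 (3.89), the metallothionein Mt1 (3.79) and the stress cytokine Gdf15 (3.74). Igfbp1, a secreted liver protein, reached 696 ± 133 FPKM from 38.2 ± 8.27 FPKM. The 12 largest falls held 6 Mup genes (Mup15, Mup7, Mup11, Mup17, Mup8 and Mup19), with log2 changes of -3.79, -3.69, -3.53, -3.08, -2.84 and -2.77. Reads of these genes are uncertain one by one because the family is near-identical, but together the 22 listed Mup genes took 2.38% to 3.27% of the reads of the control samples and 0.518% to 0.990% of those of the alcohol samples. The other falls were Cfd, the complement factor also known as adipsin (-3.39), the uridine phosphorylase Upp2 (-3.31), the steroid dehydrogenase Hsd3b5 (-3.07), the glucuronosyltransferase Ugt2b38 (-2.90), the ribonuclease Ang (-2.83) and Keg1 (-2.73). Cfd had a larger change than Mup15 as a ratio of mean FPKM, from 13.4 ± 10.1 to 0.101 ± 0.108 FPKM, 0.00753 of the control mean against 0.0761. Without alcohol replicate 4 its alcohol mean was 0.0565 ± 0.0747 FPKM (SD, n = 3). Ang shares exon sequence with Rnase4 on the same strand, so its reads are uncertain. In GENCODE M21 on GRCm38, Cyp2b10 lies on chromosome 7 from 25897620 to 25926624 (plus strand) and Atf3 on chromosome 1 from 191170296 to 191218039 (minus strand). Trib3 lies on chromosome 2 from 152337422 to 152344032 (minus strand) and Mup15 on chromosome 4 from 61435790 to 61439743 (minus strand), and all are protein-coding.

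Of 9228 genes tested by limma, 4080 were higher and 1203 lower with alcohol, and 847 of these changed at least 2-fold on the log2 scale, 652 upward and 195 downward. The groups did not overlap for 4636 genes (50.2%), against 2.86% by chance. The median log2 change over all tested genes was 0.24, so most genes lay somewhat higher. With median-of-ratios scaling the median was -0.003 and the split became 2386 higher and 2446 lower (49.4% higher against 77.2%), and with quantile normalization it became 2221 and 2307 (49.1% higher). Both of these settings centre the samples by construction, which fixes a split near even. With each library scaled to its reads outside the 100 most abundant genes, which does not centre, 3804 genes were higher and 1761 lower (68.4% higher, median 0.163). On the TPM scale the surplus grew, to 4867 higher and 814 lower (85.7% higher, median 0.397). Once a gene length trend was removed there were 4435 and 988 (81.8% higher, median 0.26). That removal keeps the overall level of each sample by construction, so it cannot show whether gene length causes the surplus. Changes are to be read relative to these shifts.

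**Figure D1:**
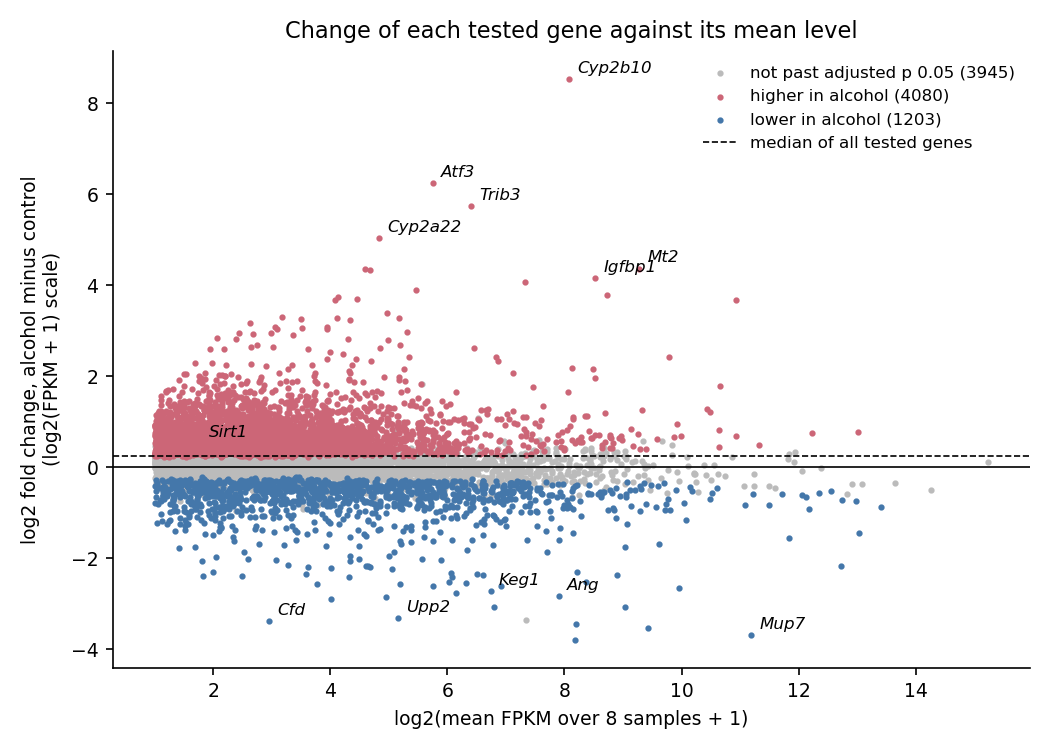
Log2 change of each of the 9228 tested genes (alcohol minus control, log2(FPKM + 1) scale) against log2 of its mean FPKM over the 8 samples plus 1. Red points (4080) were higher and blue points (1203) lower at an adjusted p under 0.05, grey points did not pass, the solid line is 0 and the dashed line the median of 0.24.

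Of the genes named in the study's title, Sirt1 was higher with alcohol, H19 was close to its detection limit and the miR-22 host transcript showed no difference larger than the replicate spread. Sirt1 stood at 1.80 ± 0.34 FPKM in controls and 3.07 ± 0.67 FPKM with alcohol (SD, n = 4 per group), and all 4 alcohol samples lay above all 4 controls. Its log2 change was 0.54 ± 0.14 (SE), with a limma adjusted p of 0.0063 and an exact permutation p of 0.0286, the smallest that 4 against 4 can give. H19 stood at 0.190 ± 0.0734 FPKM in controls and 0.0775 ± 0.0670 FPKM with alcohol, from 9 to 23 reads per control library and 1 to 15 per alcohol library. Its log2 change was -0.14 ± 0.06 (SE), with a limma adjusted p of 0.0908 and an exact permutation p of 0.0857, and 3 of the 4 alcohol samples lay below all controls. Without alcohol replicate 3 its alcohol mean was 0.0465 ± 0.0308 FPKM (SD, n = 3). Relative to the library totals, H19 had 0.411 times as many reads with alcohol (95% Poisson interval 0.251 to 0.657, counting error only). Mir22hg stood at 10.6 ± 2.94 FPKM in controls and 9.49 ± 1.29 FPKM with alcohol, with a limma adjusted p of 0.599 and an exact permutation p of 0.714.

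H19 (lincRNA) lies on chromosome 7 from 142575529 to 142578143 (minus strand) and its exons include the precursor Mir675. Sirt1 (protein-coding) lies on chromosome 10 from 63319005 to 63381704 (minus strand), and Mir22hg (processed transcript) lies on chromosome 11 from 75461539 to 75466676 (plus strand), all on GRCm38. Exons of Mir22hg overlap Tlcd2 on the same strand, so some of its reads are uncertain whether or not strand was used. Exons of Sirt1 overlap Gm16145 on the other strand, so some of its reads are uncertain where strand was not used. With quantile normalization the log2 change of Sirt1 was 0.21 and did not pass (limma adjusted p = 0.17, range over the alternatives 0.00263 to 0.17). With median-of-ratios scaling the log2 change of Sirt1 was 0.33 and only just passed (limma adjusted p = 0.0497). H19 passed with median-of-ratios scaling (-0.18, limma adjusted p = 0.0426) and without alcohol replicate 3 (-0.18, adjusted p = 0.0334), and its range over the alternatives was 0.0334 to 0.199. Without control replicate 2 the log2 change of Mir22hg was 0.01, against -0.12 with all samples.

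**Figure D2:**
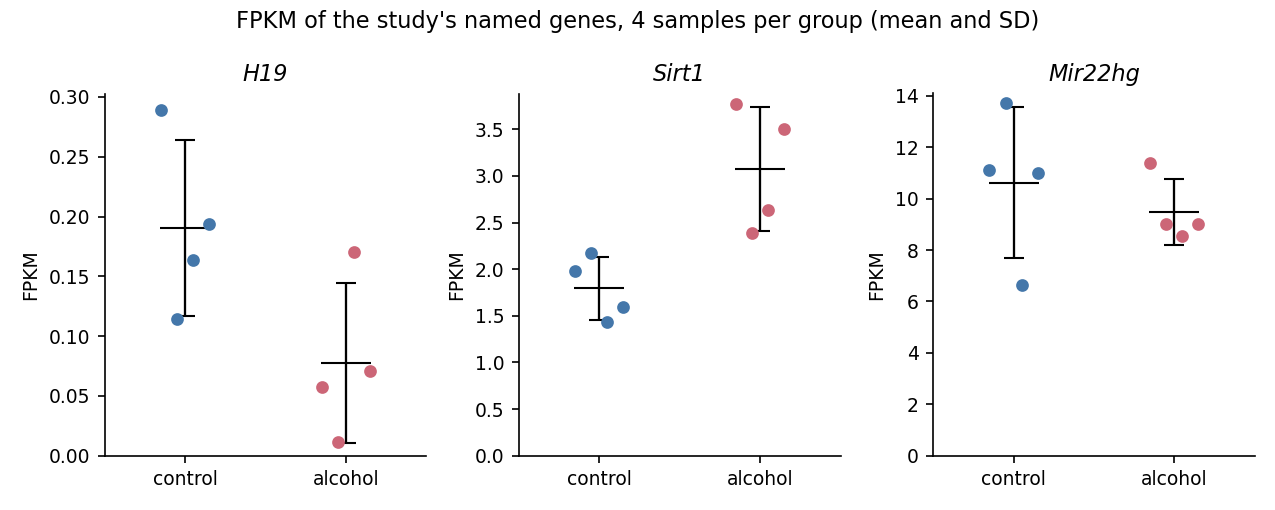
FPKM of H19, Sirt1 and Mir22hg in each of the 4 control (blue) and 4 alcohol (red) samples, each panel with its own axis from 0. Horizontal bars are means and whiskers 1 SD.

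Genes that process drugs and other foreign compounds rose together, while several ethanol-metabolizing enzymes fell. Counts given below over the other scalings are the lowest and highest with median-of-ratios scaling, quantile normalization, TPM scale and removal of a gene length trend. Over all 9228 tested genes 4080 rose and 1203 fell, so a list with a like share of rises does not stand out from the other genes. Camera compares each list with those other genes. In the xenobiotic metabolism list 17 of 21 tested genes rose and none fell (over the other scalings 13 to 19 rose and 0 fell, camera adjusted p = 0.000483, and adjusted p = 0.0881 with an estimated correlation). Beside Cyp2b10, Cyp2c29 rose from 282 ± 54.7 to 3610 ± 582 FPKM, Cyp2c55 from 0.684 ± 0.338 to 5.85 ± 1.41 FPKM and Cyp2c54 from 129 ± 25.4 to 405 ± 35.3 FPKM (SD, n = 4 per group), although reads within the Cyp2b and Cyp2c families are uncertain. In the list of ethanol and acetaldehyde metabolism 2 of 13 rose and 4 fell (1 and 4 adjusted over the list alone; over the other scalings 0 to 2 rose and 3 to 9 fell, camera adjusted p = 0.00189 downward, adjusted p = 0.419 with an estimated correlation). The alcohol dehydrogenase Adh4 fell from 54.0 ± 6.45 to 16.8 ± 1.38 FPKM, the peroxisomal catalase Cat from 978 ± 110 to 530 ± 11.8 FPKM and Aldh9a1 from 86.9 ± 9.72 to 57.4 ± 7.35 FPKM. The aldehyde dehydrogenase Aldh1a1 rose from 328 ± 28.2 to 468 ± 88.2 FPKM, a call lost with median-of-ratios scaling. Cyp2e1, the ethanol-oxidizing cytochrome, which was chosen after its values were seen, fell from 6240 ± 753 to 4227 ± 701 FPKM (limma adjusted p = 0.0153). Adh1 and Aldh2, chosen in the same way, did not pass. Adh1 stood at 1594 ± 148 FPKM in controls and 1322 ± 123 FPKM with alcohol (limma adjusted p = 0.105). Aldh2 stood at 524 ± 63.0 and 424 ± 20.4 FPKM (adjusted p = 0.0534). Both passed as lower with median-of-ratios scaling (adjusted p = 0.00932 and 0.00364). In the lists below, the counts adjusted over the list alone were the same as those over all genes unless a second count is given.

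Stress response genes rose in both the integrated stress response and the NRF2 lists, although camera called neither list. Of 17 tested genes of the endoplasmic reticulum and integrated stress response list 10 rose and 2 fell (10 and 3 adjusted over the list alone; over the other scalings 9 to 10 rose and 1 to 4 fell, camera adjusted p = 0.259). Besides Atf3 and Trib3 these included Ddit3, the transcription factor CHOP, from 1.37 ± 0.230 to 30.4 ± 11.9 FPKM, and the serine synthesis enzyme Psat1 from 0.403 ± 0.242 to 4.89 ± 1.28 FPKM. Of 22 targets of NRF2, the transcription factor of oxidant defence, 14 rose and 1 fell (over the other scalings 11 to 15 rose and 1 to 3 fell, camera adjusted p = 0.0511). Hmox1 rose from 4.76 ± 1.58 to 82.1 ± 9.07 FPKM, Gstm3 from 16.2 ± 4.04 to 301 ± 123 FPKM, the exporter Abcc4 from 0.0704 ± 0.0129 to 5.65 ± 1.63 FPKM and sulfiredoxin Srxn1 from 7.46 ± 1.44 to 42.5 ± 12.02 FPKM. Among 19 genes of the antioxidant list 2 rose, the metallothioneins Mt1 and Mt2, which are metal-binding proteins and not enzymes, and 6 fell. Those that fell included Gpx1, a glutathione peroxidase, from 1492 ± 161 to 668 ± 46.5 FPKM, and Cat. Over the other scalings 2 to 6 rose and 5 to 11 fell. Camera called this list downward (adjusted p = 0.0132, adjusted p = 0.518 with an estimated correlation) with a median log2 change of -0.15 and a mean of 0.19, which differ in sign. The median was 0.04 once a gene length trend was removed. Of 16 immediate early genes 8 rose and 1 fell (over the other scalings 6 to 10 rose and 0 to 1 fell, camera adjusted p = 0.193), with Jund from 15.2 ± 1.43 to 60.5 ± 14.3 FPKM, Klf6 from 0.966 ± 0.228 to 13.4 ± 10.8 FPKM and Ier3 from 0.445 ± 0.217 to 1.91 ± 0.700 FPKM. Without alcohol replicate 1 the alcohol mean of Klf6 was 7.98 ± 0.715 FPKM (SD, n = 3). Of 13 genes of p53 signalling and cell death 5 rose and 1 fell (over the other scalings 4 to 5 rose and 1 to 4 fell, camera adjusted p = 0.902), with Cdkn1a from 1.34 ± 0.378 to 47.8 ± 17.3 FPKM, Gdf15 from 1.45 ± 0.823 to 31.7 ± 11.6 FPKM and Bcl2l11 from 0.437 ± 0.154 to 1.74 ± 0.245 FPKM, while the caspase Casp8 fell from 10.1 ± 1.63 to 4.14 ± 0.524 FPKM. Of 13 heat shock genes 1 rose and 6 fell (over the other scalings 0 to 2 rose and 5 to 6 fell, camera adjusted p = 0.0119 downward, adjusted p = 0.474 with an estimated correlation), including the chaperones Hspa8, from 587 ± 60.8 to 317 ± 50.9 FPKM, Hsph1, Hspe1 and Dnajb1. The Hspe1 call was lost once a gene length trend was removed. The median of the p53 list was 0.09, and -0.07 with median-of-ratios scaling. The heat shock median was -0.09, and 0.05 on the TPM scale.

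Lipid genes moved in both directions, and more genes of fatty acid oxidation and of cholesterol synthesis fell than rose. Of 23 PPARA targets and fatty acid oxidation genes 14 fell and 1 rose (over the other scalings 1 to 2 rose and 10 to 18 fell, camera adjusted p = 9.2e-07 downward, adjusted p = 0.419 with an estimated correlation). The fatty acid binding protein Fabp1 fell from 11140 ± 2786 to 2429 ± 271 FPKM, the carnitine carrier Slc25a20 from 91.4 ± 7.87 to 49.7 ± 3.50 FPKM and Cpt2 from 58.5 ± 4.95 to 33.5 ± 1.20 FPKM, while Pdk4, an inhibitor of glucose oxidation, rose from 0.399 ± 0.170 to 4.39 ± 1.61 FPKM. Of 24 cholesterol synthesis genes 10 fell and 1 rose (over the other scalings 1 to 2 rose and 7 to 16 fell, camera adjusted p = 1.23e-05 downward, adjusted p = 0.511 with an estimated correlation), with Stard4, a sterol transporter, from 17.5 ± 4.28 to 6.88 ± 0.321 FPKM, Tm7sf2, Nsdhl and Insig1. Of 20 genes of fatty acid and triglyceride synthesis 5 rose and 6 fell (over the other scalings 3 to 6 rose and 5 to 7 fell, camera adjusted p = 0.11). The transcription factor Srebf1 fell from 35.1 ± 7.59 to 11.5 ± 1.31 FPKM and the desaturase Fads2 from 362 ± 124 to 115 ± 22.8 FPKM, while Acaca, which makes malonyl-CoA, rose from 8.78 ± 0.980 to 18.99 ± 1.40 FPKM and the triglyceride-forming enzyme Dgat2 from 251 ± 34.1 to 573 ± 44.4 FPKM. The median of this list was 0.11, its mean -0.10 and its camera direction downward, and the median was -0.19 with median-of-ratios scaling. Of 16 lipid droplet and lipid uptake genes 4 rose and 5 fell (over the other scalings 3 to 5 rose and 4 to 6 fell, camera adjusted p = 0.101). The fatty acid transporter Cd36 rose from 4.90 ± 1.59 to 20.3 ± 4.73 FPKM and Hilpda from 1.75 ± 0.215 to 4.33 ± 0.708 FPKM, while the lipase Mgll and the droplet protein Fitm1 fell. That list's median was -0.08, and 0.05 on the TPM scale, and its mean was 0.02.

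Of 18 bile acid genes 5 rose and 5 fell (over the other scalings 2 to 5 rose and 3 to 7 fell, camera adjusted p = 0.0714). The exporter Abcc3 rose from 22.9 ± 6.80 to 65.0 ± 3.79 FPKM (SD, n = 4 per group), while the hydroxylase Cyp7b1 fell from 153 ± 83.9 to 25.97 ± 3.32 FPKM, the sterol transporter Abcg5 from 40.3 ± 5.07 to 19.7 ± 4.97 FPKM and the nuclear receptor Nr0b2 from 22.6 ± 14.4 to 2.82 ± 2.03 FPKM. The median of the bile acid list was -0.08, and 0.07 on the TPM scale. Of 16 gluconeogenesis and glycogen genes 7 rose and 2 fell (over the other scalings 5 to 8 rose and 2 to 3 fell, camera adjusted p = 0.902). Besides Igfbp1, the glycogen phosphatase subunit Ppp1r3b rose from 34.0 ± 5.43 to 89.4 ± 26.5 FPKM. Pck1, the enzyme that commits carbon to gluconeogenesis, fell from 1181 ± 154 to 381 ± 142 FPKM and the glycogen synthase Gys2 from 148 ± 16.0 to 70.8 ± 7.20 FPKM.

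Interferon-response genes were lower with alcohol. Of 16 tested genes 12 fell and none rose, with a median log2 change of -0.79 (over the other scalings 0 rose and 11 to 16 fell, camera adjusted p = 2.55e-10, and adjusted p = 0.0881 with an estimated correlation). Irf7, a transcription factor of the interferon response, fell from 19.5 ± 0.511 to 8.49 ± 0.497 FPKM, Ifit1 from 3.11 ± 0.528 to 0.912 ± 0.171 FPKM, Ifi47 from 10.9 ± 1.32 to 3.50 ± 0.856 FPKM and Ifi27 from 57.8 ± 9.51 to 23.1 ± 3.01 FPKM. Of 12 inflammatory cytokine and NF-kB genes 5 rose and 2 fell (over the other scalings 4 to 6 rose and 1 to 3 fell, camera adjusted p = 0.902). Il1a rose from 0.424 ± 0.176 to 1.96 ± 0.299 FPKM, the NF-kB subunits Rela and Nfkb1 from 9.67 ± 1.37 to 24.1 ± 4.26 and from 2.95 ± 0.152 to 5.22 ± 0.447 FPKM, and the adhesion molecule Icam1 from 2.92 ± 0.929 to 9.71 ± 3.83 FPKM. The median of the inflammatory list was 0.31, and -0.02 with quantile normalization. Another 15 genes of this list lay under the expression minimum. In the limma fit without it 2 of them, chosen after their values were seen, rose: Tnfaip3 from 0.166 ± 0.0347 to 0.744 ± 0.322 FPKM (adjusted p = 0.00819) and Tlr4 from 0.131 ± 0.0402 to 0.247 ± 0.0464 FPKM (adjusted p = 0.0175). The other 13, Tnf and Il6 among them, did not pass. Of 25 acute phase genes 4 rose and 5 fell (4 and 3 adjusted over the list alone; over the other scalings 3 to 5 rose and 3 to 8 fell, camera adjusted p = 0.024 downward, adjusted p = 0.742 with an estimated correlation). Serpina3m rose from 132 ± 35.1 to 586 ± 104 FPKM and Saa3 fell from 17.2 ± 8.84 to 5.19 ± 1.16 FPKM, both in near-identical families, while the lipopolysaccharide-binding protein Lbp and the pentraxin Apcs rose.

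Of 24 nuclear genes of oxidative phosphorylation 9 fell and none rose (0 and 7 adjusted over the list alone; over the other scalings 0 to 2 rose and 5 to 19 fell, camera adjusted p = 9.89e-06 downward, adjusted p = 0.419 with an estimated correlation). The complex I subunit Ndufb3 fell from 67.2 ± 10.9 to 28.6 ± 3.27 FPKM, Ndufs3 from 141 ± 19.2 to 92.8 ± 4.72 FPKM, Ndufa1 from 122 ± 25.5 to 72.3 ± 18.1 FPKM and the complex III subunit Uqcrfs1 from 176 ± 22.1 to 107 ± 8.60 FPKM. The median of this list was -0.33, and 0.04 once a gene length trend was removed. Of 26 cytosolic ribosomal protein genes 11 rose and none fell (10 and 0 adjusted over the list alone; over the other scalings 6 to 23 rose and 0 to 1 fell, camera adjusted p = 0.24). The lowest count, 6, came with median-of-ratios scaling and the highest, 23, once a gene length trend was removed. Rpl3 rose from 181 ± 37.9 to 384 ± 27.1 FPKM, and Rpl10a, Rpl4 and Rpl5 rose by less. Of 18 genes of sirtuins and NAD metabolism 1 rose, Sirt1, and 5 fell (1 and 3 adjusted over the list alone; over the other scalings 0 to 1 rose and 3 to 13 fell, camera adjusted p = 0.000483 downward, adjusted p = 0.177 with an estimated correlation). The count that fell was largest with median-of-ratios scaling. The nucleolar sirtuin Sirt7 fell from 14.3 ± 0.955 to 9.55 ± 0.972 FPKM, the kinase Nmrk1 from 31.5 ± 4.34 to 18.1 ± 1.13 FPKM and Haao, of NAD synthesis from tryptophan, from 113 ± 14.03 to 70.7 ± 4.86 FPKM. Of 14 circadian clock genes 7 rose and 1 fell (over the other scalings 3 to 8 rose and 1 to 3 fell, camera adjusted p = 0.902). Cry1 rose from 2.19 ± 0.0789 to 7.57 ± 0.507 FPKM and Clock from 1.22 ± 0.162 to 4.37 ± 0.568 FPKM, while Dbp fell from 52.3 ± 9.49 to 13.6 ± 0.959 FPKM. Another 3 clock genes lay under the expression minimum. In the limma fit without it 2 of them, chosen after their values were seen, rose and 1 did not pass. Bmal1 rose from 0.0297 ± 0.0156 to 0.706 ± 0.058 FPKM (adjusted p = 2.5e-05) and Npas2 from 0.00686 ± 0.00566 to 0.0716 ± 0.019 FPKM (adjusted p = 0.0019). Of 6 tested cell cycle genes 1 rose, Cdkn1a, and 2 fell, the replication factors Mcm6 and Pcna, of which Pcna lost its call once a gene length trend was removed (over the other scalings 1 to 3 rose and 2 to 3 fell, camera adjusted p = 0.399). Their median log2 change was 0.07, their mean 0.62 and the camera direction downward, and the median was -0.15 with median-of-ratios scaling. Another 15 cell cycle genes lay under the expression minimum. In the limma fit without it 4 of them, chosen after their values were seen, fell (adjusted p from 0.0010 to 0.0033). These were Cdk1, from 0.444 ± 0.081 to 0.12 ± 0.041 FPKM, Mcm5, from 0.974 ± 0.30 to 0.24 ± 0.039 FPKM, Ccne1 and Mki67. The other 11 did not pass.

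**Figure D3:**
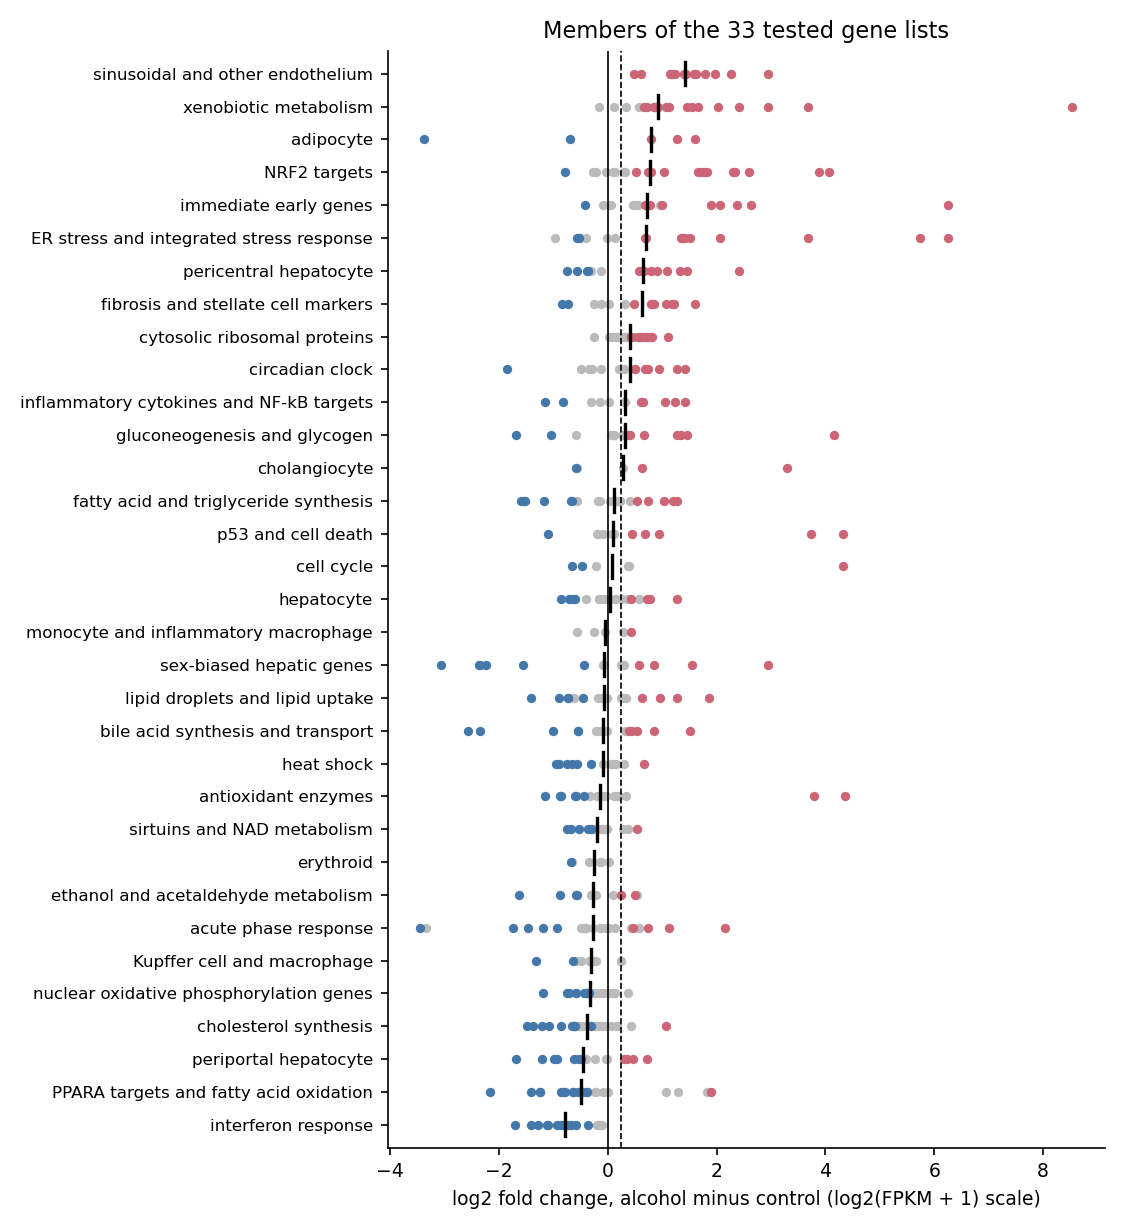
Log2 change (alcohol minus control, log2(FPKM + 1) scale) of every tested member of the 33 tested lists, sorted by median. Red points rose and blue points fell at an adjusted p under 0.05, grey points did not pass, black bars are list medians, the solid line is 0 and the dashed line the median of all genes, 0.24.

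Markers of endothelial cells were higher in every alcohol sample, while those of Kupffer cells were not. All 14 tested endothelial markers rose, with a median log2 change of 1.42 (over the other scalings 12 to 14 rose and 0 fell, camera adjusted p = 3.62e-06, and adjusted p = 0.419 with an estimated correlation). The hyaluronan receptor Lyve1 rose from 0.478 ± 0.231 to 10.3 ± 1.33 FPKM (SD, n = 4 per group), Bmp2 from 1.18 ± 0.469 to 9.31 ± 0.486 FPKM, Oit3 from 1.86 ± 0.394 to 10.3 ± 1.48 FPKM and the VEGF receptor Kdr from 0.882 ± 0.227 to 4.82 ± 0.655 FPKM. Of 14 fibrosis and stellate cell markers 8 rose and 2 fell (over the other scalings 6 to 9 rose and 2 fell, camera adjusted p = 0.398), with the basement membrane collagen Col4a1 from 2.21 ± 0.252 to 6.42 ± 0.591 FPKM, the retinol-storing enzyme Lrat from 1.55 ± 0.391 to 6.78 ± 1.66 FPKM, Rgs5 from 4.03 ± 0.423 to 10.5 ± 2.05 FPKM and Reln from 1.86 ± 0.282 to 4.12 ± 0.115 FPKM. The 2 that fell were Acta2 (limma adjusted p = 0.00987) and the collagen Col3a1 (adjusted p = 0.0346). The collagens Col1a1 and Col1a2 did not pass (adjusted p = 0.301 and 0.927). These last genes were chosen after their values were seen. Of 11 Kupffer cell and macrophage markers 2 fell, Mpeg1 and Cd68, and none rose (0 and 1 adjusted over the list alone; over the other scalings 0 rose and 1 to 3 fell, camera adjusted p = 0.0119 downward, adjusted p = 0.658 with an estimated correlation). Mpeg1 fell from 12.6 ± 4.00 to 4.33 ± 1.14 FPKM, while Cd68 fell from 4.81 ± 1.86 to 2.60 ± 0.569 FPKM. The Cd68 call was lost without control replicate 1, 3 or 4 and without alcohol replicate 2, 3 or 4 (limma adjusted p from 0.0532 to 0.0964). It was also lost on the TPM scale and once a gene length trend was removed. Of 5 monocyte markers 1 rose, Cd9, and none adjusted over the list alone (over the other scalings 0 to 1 rose and 0 to 2 fell, camera adjusted p = 0.399). Cd9 stood at 13.1 ± 1.67 FPKM in controls and 18.0 ± 3.60 FPKM with alcohol. Its call was lost with median-of-ratios scaling (limma adjusted p = 0.479) and with quantile normalization (adjusted p = 0.323). The Cd9 call was also lost without control replicate 1, 2 or 3 or alcohol replicate 2 or 4 (limma adjusted p from 0.0568 to 0.0836). The monocyte median was -0.06, and 0.03 on the TPM scale. Of 5 cholangiocyte markers 2 rose and 1 fell (2 and 2 adjusted over the list alone; over the other scalings 2 rose and 1 to 2 fell, camera adjusted p = 0.902), led by the keratin Krt23, from 0.710 ± 0.483 to 15.4 ± 2.09 FPKM, while Cdh1 fell. The cholangiocyte median was 0.28 but its camera direction was downward, and the median was -0.03 with quantile normalization.

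Among hepatocyte lists, 9 of 15 pericentral markers rose and 4 fell (over the other scalings 7 to 9 rose and 1 to 6 fell, camera adjusted p = 0.902), with Axin2, a Wnt target, from 0.503 ± 0.102 to 2.78 ± 0.296 FPKM, the amino acid transporter Slc1a4 from 0.515 ± 0.125 to 3.17 ± 0.684 FPKM, and Cyp2a5 and Cyp2c37 also higher. Cyp2a5 and Cyp2c37 belong to the xenobiotic list too. The 4 that fell were Cyp2e1, Oat, Gulo and Lect2 (limma adjusted p from 0.000678 to 0.0312), and Glul did not pass (adjusted p = 0.1025). These last 5 genes were chosen after their values were seen. Of 16 periportal markers 4 rose and 7 fell (over the other scalings 0 to 4 rose and 4 to 10 fell, camera adjusted p = 0.0013 downward, adjusted p = 0.419 with an estimated correlation). The urea cycle enzyme Otc fell from 132 ± 13.4 to 56.8 ± 6.27 FPKM, Cyp2f2 from 599 ± 84.2 to 315 ± 60.6 FPKM and Pigr from 200 ± 36.3 to 131 ± 28.7 FPKM, a call lost on the TPM scale. With median-of-ratios scaling no periportal marker rose. Of 18 general hepatocyte markers 4 rose and 4 fell (over the other scalings 2 to 6 rose and 3 to 6 fell, camera adjusted p = 0.179): Ahsg rose from 6102 ± 481 to 10510 ± 853 FPKM and Tat from 373 ± 90.0 to 909 ± 279 FPKM, and Apoa1 fell from 13980 ± 1486 to 7633 ± 325 FPKM and Ttr from 5513 ± 1116 to 3468 ± 258 FPKM. Their median and mean were both 0.05 while the camera direction was downward, and the median was -0.25 with median-of-ratios scaling. Of 6 erythroid genes 1 fell, Alas2, from 56.1 ± 4.42 to 34.8 ± 4.81 FPKM (over the other scalings 0 rose and 1 to 2 fell, camera adjusted p = 0.0369 downward, adjusted p = 0.419 with an estimated correlation), with a median of -0.25, and 0.16 once a gene length trend was removed. Of 5 adipocyte markers 3 rose, among them Fabp4 from 3.98 ± 2.15 to 14.2 ± 6.66 FPKM and Cidec from 3.396 ± 2.09 to 9.05 ± 2.89 FPKM, and 2 fell, Cfd and Car3 (over the other scalings 2 to 3 rose and 2 fell, camera adjusted p = 0.602, median 0.79, mean -0.09, camera direction downward).

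Of 14 sex-biased liver genes 4 rose and 6 fell (over the other scalings 2 to 5 rose and 5 to 8 fell, camera adjusted p = 0.0134 downward, adjusted p = 0.207 with an estimated correlation). The male-biased Hsd3b5 fell from 198 ± 29.4 to 23.5 ± 7.83 FPKM, Cyp4a12a from 164 ± 32.2 to 30.7 ± 3.13 FPKM and Cyp4a12b from 53.8 ± 13.7 to 10.4 ± 0.788 FPKM, with reads of the Cyp4a pair uncertain. The female-biased Cyp2a4 rose from 0.686 ± 0.291 to 13.2 ± 7.48 FPKM. Its recovered length, 1715 bases, equals that of Cyp2a5, which rose from 267 ± 14.03 to 1500 ± 542 FPKM. Whether reads of Cyp2a5 were given to Cyp2a4 was not tested, so the rise of Cyp2a4 is uncertain. The list's median was -0.08, and 0.05 on the TPM scale. The list mixes male-biased, female-biased and Y chromosome genes, so its median and camera direction do not measure a shift in sex bias. Its other rises, named after their values were seen, were Cyp2b9, Ddx3y and Uty (limma adjusted p = 0.0221, 0.00515 and 0.00246). Ddx3y and Uty are Y chromosome genes. The male-biased Elovl3 and Slco1a1, named in the same way, did not pass (adjusted p = 0.1465 and 0.706).

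Several lists had fewer than 5 tested members and were not compared as lists. Of 4 tested genes of the imprinted network, which holds H19, Dcn rose from 48.6 ± 12.6 to 101 ± 17.1 FPKM (SD, n = 4 per group) and Igf2r from 2.85 ± 0.620 to 4.26 ± 0.451 FPKM. The Igf2r call was lost with median-of-ratios scaling and with quantile normalization. The median of the imprinted list was 0.07, and -0.19 with median-of-ratios scaling. Neither of 2 tested neutrophil markers passed: S100a9 stood at 1.97 ± 0.713 FPKM in controls and 6.09 ± 8.27 FPKM with alcohol, and S100a8 at 1.17 ± 0.468 and 4.00 ± 6.50 FPKM. Without alcohol replicate 1 their alcohol means were 1.97 ± 0.870 and 0.754 ± 0.565 FPKM (SD, n = 3). The T and NK cell list had Ccl5, which fell from 4.60 ± 3.11 to 1.56 ± 1.39 FPKM. The Ccl5 call was lost without control replicate 3 or 4 and without alcohol replicate 1 or 3 (limma adjusted p from 0.0736 to 0.105), and once a gene length trend was removed. The B and plasma cell list had 2 tested genes, of which Jchain fell from 1.61 ± 0.164 to 0.921 ± 0.168 FPKM. Under the expression minimum, 1 of 13 T and NK cell markers and 2 of 6 B and plasma cell markers fell in the limma fit without it, and none rose. The genes that fell are named here after their values were seen. Cd4 fell from 0.690 ± 0.156 to 0.0843 ± 0.0501 FPKM (adjusted p = 0.000555), and the B cell genes Cd79a from 0.796 ± 0.244 to 0.187 ± 0.186 FPKM (adjusted p = 0.0104) and Cd79b from 0.928 ± 0.322 to 0.118 ± 0.107 FPKM (adjusted p = 0.00312). The exocrine pancreas list had Cela1, which fell from 13.5 ± 2.66 to 8.62 ± 1.90 FPKM, a call lost once a gene length trend was removed. Of the 10 genes of that list, 8 had 0 FPKM in every alcohol sample and in control replicates 2 and 3, and were above 0 only in control replicates 1 and 4. The colipase Clps, for instance, stood at 4.18 and 0.644 FPKM there. The adipocyte gene Adipoq was also highest in control replicates 1 and 4 (0.583 and 0.767 FPKM), whereas Cfd was highest in 2 and 3 (25.3 and 17.9 FPKM). Clps and Adipoq were chosen after their values were seen, lay under the expression minimum and did not pass without it. The list of mitochondrially encoded genes had 0 genes under the symbols fixed for it; the table gives those genes under other symbols. Camera called 15 of 33 lists, 2 upward and 13 downward, relative to the other genes, and with an estimated correlation it called none.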

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

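Of the tests below, the comparison of endothelial with Kupffer markers and the test on Ddx3y were chosen only after the results were seen. So was the comparison of the endothelial markers with each other. The scaling test without abundant genes replaced an earlier one by median-of-ratios scaling, whose result had been seen and which centring fixes in advance. In 19 of 280 groups of 4 samples, 1 sample stood apart from the other 3. Chance marks about 1 in 20 such groups, and genes that move together are not independent. The value given is the gap to the nearest sample divided by the range of the group.

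In 11 of the 19 groups the sample was alcohol replicate 1, each time the highest. For Atf3, a stress transcription factor, the value was 0.955, with 207 FPKM against 68.3 to 74.5 FPKM in the other alcohol samples. It was 0.937 for Klf6, 0.931 for Sgk1, 0.858 for Ddit3, 0.851 for Cyp2b10, 0.837 for Mir22hg and 0.835 for Rela. Among markers of other cells it was 0.974 for Mpeg1, 0.919 for S100a8, 0.900 for S100a9 and 0.896 for Cidec. S100a9, a neutrophil marker, stood at 18.4 FPKM in that sample against 1.14 to 2.88 FPKM, and S100a8 at 13.7 against 0.133 to 1.24 FPKM. Without alcohol replicate 1, 3754 genes were higher and 1073 lower. No explanation for this sample was tested.

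In the other groups, alcohol replicate 2 was high for Ugt2b38 (0.876), and alcohol replicate 3 for Acaca (0.902) and Abcg5 (0.851). Control replicate 4 was high for Mup8 (0.892) and Mup19 (0.916) and low for Aldh9a1 (0.861). Control replicate 2 was high for Adh4 (0.843) and control replicate 1 for Pigr (0.923).

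Genes outside the tested set also differed. Of 11821 genes under the expression minimum, 1500 were called higher and 365 lower by limma when no minimum was used. Listed at 0 reads in all 4 controls and at 3 or more in every alcohol sample were 3 genes, named here after their values were seen. Vmn2r3, a vomeronasal receptor gene on chromosome 3 from 64257215 to 64289709 (minus strand, GRCm38), had 494 to 1052 reads per alcohol sample. Gm40156 had 13 to 25 reads, and Gm49227, which is antisense to App, 4 to 21.

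More genes were higher than lower with alcohol (4080 against 1203). With each library scaled to its reads outside the 100 most abundant genes the median log2 change was 0.163 (0.244 with all genes), between the bounds set for and against scaling as the cause. With 10 genes left out it was 0.23 and with 500 it was 0.075 (58.7% of calls higher), so the answer turns on how many are left out. Among called genes in the shortest of 3 equal classes of gene length 54.6% were higher, against 91.9% in the longest class, also between the bounds set. Scaling, gene length and a wide rise with alcohol therefore cannot be told apart, because no transcript of known amount is measured here.

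All 14 endothelial markers were higher with alcohol. The endothelial minus Kupffer list mean differed by 1.85 between groups, with every alcohol sample above every control (exact permutation p = 0.0286, the smallest of 70 assignments). That argues against a lower share of hepatocytes raising all other cells alike. Of 10000 random lists of like length and expression 0% had a median as high (highest 0.89 against 1.42), and 14 markers were higher with median-of-ratios scaling, which argues against length and scaling. The 14 markers did not rise alike. With median-of-ratios scaling their log2 changes ran from 0.29 ± 0.09 (SE) for Stab2 to 2.75 ± 0.14 for Lyve1. That argues against a larger share of otherwise unchanged endothelial cells as the only source of the rise. A change in endothelial cells, with or without a change in their share, may explain it, and stays untested.

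Male-biased liver genes such as Hsd3b5 and the Mup genes were lower with alcohol, although the male-biased Elovl3 and Slco1a1 did not pass. The lowest Ddx3y value, from the Y chromosome, among alcohol samples was 142% of the control mean, which argues against female mice in that group. The summed share of reads in all listed Mup genes differed by -1.9 on the log2 scale, so the fall does not come from reads moving between Mup genes. A response of these genes to alcohol may explain the fall, as a hypothesis found and examined on the same data.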

How the results depend on the processing

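Voom on the recovered reads and removal of a gene length trend were chosen after seeing the data. Under the alternatives, 288 called genes, H19 and Mir22hg gave 6019 values: 5641 stayed on the same side of the threshold, 373 lost the call (162 higher, 211 lower with alcohol), 2 gained it, both of H19, and 3 reversed. Of the 5641, only 3 changed sign, all of Mir22hg, which was not called: 0.0189 on the TPM scale, 0.05632 with the length trend removed and 0.01087 without control replicate 2, against -0.1164. The 290 genes leave out 224 listed genes without a call. Of those, 71 gained one with median-of-ratios scaling (all lower), 41 with quantile normalization (8 higher, 33 lower), 31 on the TPM scale (all higher), 35 with the length trend removed (27 higher, 8 lower), 79 with sample weights (33 higher, 46 lower) and 42 with a replicate block (19 higher, 23 lower). Genes changed at least 2-fold numbered 1416 with a pseudocount of 0.1, 319 with 5, 533 at a minimum of 5 FPKM, 1357 on the TPM scale and 1507 with voom, against 847. The higher count was 1981 at a minimum of 5 FPKM, where fewer genes are tested. Higher and lower counts were 2221 and 2307 with quantile normalization, 2386 and 2446 with median-of-ratios scaling and 4867 and 814 on the TPM scale. Lists called were 9 with quantile normalization and 0 with an estimated correlation, where fry called 20. Sirt1 was 0.2064 with quantile normalization (limma adjusted p = 0.17, range 0.00263 to 0.17). H19 was -0.1768 with median-of-ratios scaling (adjusted p = 0.0426, range 0.0334 to 0.199), and -0.1841 (without alcohol replicate 3) to -0.1045 (without control replicate 1) with 1 sample left out. Reversed were Adh7 (-0.0821, quantile normalization), Hsd17b13 (-0.000254, median-of-ratios scaling), and Ndufa2 (0.01336, length trend removed). For these changes the cause was not tested. Fry tests against no change and camera against the other genes, so their directions can differ without a reversal: for 6 lists camera pointed downward and fry upward. Of these fry called the cell cycle (median 0.0728) and cholangiocyte (0.2755) lists, with the same medians, and camera called none. A replicate block gave 4307 higher and 1380 lower genes, 850 changed at least 2-fold and 16 lists. Same-numbered samples correlated at 0.071 to 0.349, with 3 of 4 pairs over 0.1, and other pairs at -0.425 to 0.29; 4 of 8 samples correlated best with their own number. As not every pair passed 0.1, the numbers were not taken to pair the samples. Depth limits H19, with 1 to 23 reads per library.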

Other observations

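The groups of mitochondrially encoded, proteasome and MHC class II genes were chosen after their values were seen, among 239 symbol stems with at least 6 tested genes, and no explanation of them was tested. Of 13 mitochondrially encoded genes, listed under other symbols than those fixed for them, 6 fell and none rose, with a median log2 change of -0.60. ND2, a complex I subunit, had a log2 change of -0.74 ± 0.22 (SE, n = 4 per group; limma adjusted p = 0.0156) and ND6 of -0.99 ± 0.20. Once a gene length trend was removed 1 rose and 2 fell. Together they took 8.81 ± 2.43% of reads in controls and 6.10 ± 0.874% with alcohol (SD, n = 4 per group). Of 17 proteasome core subunits 11 fell and none rose (median -0.43), with Psmb3 at -1.24, and the immunoproteasome subunits Psmb8, Psmb9 and Psmb10 at -0.93, -1.30 and -0.84. Once a gene length trend was removed 1 rose and 7 fell. All 5 tested MHC class II genes fell (median -0.96), among them H2-Aa from 24.5 ± 5.40 to 10.5 ± 1.79 FPKM and Cd74 from 42.2 ± 7.67 to 23.9 ± 2.60 FPKM, and 4 fell once a gene length trend was removed. The B cell genes Cd79a and Cd79b, the T cell gene Cd4 and the macrophage gene Mpeg1 were lower too, but most markers of these cells did not pass. Under the expression minimum 12 of 13 T and NK cell markers and 4 of 6 B and plasma cell markers did not pass. Nor did 9 of 11 tested Kupffer cell and macrophage markers. Whether the samples held fewer of these cells was not tested.

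Genes with a site for the miR-22 seed were tested as a set, by a test fixed before its value was seen and run again, after a first value, on protein-coding transcripts alone. Of 8598 tested genes with an annotated 3' UTR of at least 50 bases, 1286 had a site. Against genes without one, of like UTR length and expression, they differed by 0.0053 on the log2 scale (exact permutation p = 0.543). That lies inside the central 95% of 380 other sequences of the same composition, -0.0742 to 0.0921, so no shift of these genes as a set was seen. The annotated 3' UTR of Sirt1 (1634 bases) has 1 site, on chromosome 10 from 63320155 to 63320161 (GRCm38), and 0 of 7 annotated H19 transcripts have one.

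The 8 samples make 35 splits of 4 against 4. For genes higher with alcohol 1 of them, the real one, gave as many (4080, highest other 1 in either direction). The same held for genes lower (1203, highest other 1) and genes changed at least 2-fold (847, highest other 1). Every other split puts samples of both groups on each side, so a wide difference between the groups holds down the counts of those splits. The real split stood apart, but 1 of 35 is the least that this test can give, so chance is not excluded. For lists called by camera 6 of the 35 splits gave as many (15, highest other 20), so chance cannot be excluded for that count.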
